A study of Homo sapiens with 12 samples.

How the data were processed

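Messenger RNA was measured in 12 libraries from BXPC3 and PANC1, 2 human cell lines of pancreatic cancer, each cultured inside collagen, in 5% gelatin methacryloyl (GelMA) or in 7.5% GelMA, with 2 libraries in each of the 6 groups. Per the labels' protocols, RNA was extracted with an RNeasy kit and libraries were made after poly-A capture. HISAT2 2.1.0 and HTSeq were used with the genome build GRCh38, also called hg38, per the submitters' processing notes. The roles and settings of these tools, the annotation, the strand setting and the library kit are not given in the sources used here.

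The deposited values were log2 RPKM (read density corrected for gene length and library size), in 1 table of 16299 Ensembl genes by 12 libraries, from which 0 columns of per-sample values were left unmapped. The offset added before the log, the gene lengths and the filter that chose the genes are not given in the sources used here. The values ran from -8.66 to 13.74, and the sorted values of all 12 libraries were equal within 0.05 log2 for the 13758 genes above the lowest 2541 ranks. The deposited values were therefore taken to be quantile normalized across all libraries, a step read from the values and not from a label. A gene that holds the same rank in every library has the same value in every library after such a step, and a change shared by most genes is removed by it. A fold change between groups in which a gene lies under 1 RPKM depends on the unknown offset.

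Read counts were not used here, and RPKM after quantile normalization keeps no library totals, so the depth of each library is unknown. No counting interval or detection limit could be given, and the error of each value was taken from the spread between libraries alone. A low RPKM is likewise not evidence that a transcript was absent.

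Gene IDs were paired with symbols through a table of gene names (16250 of 16299 IDs) and GENCODE 29 (the other 49). Positions and gene types are from GENCODE 29 on GRCh38, where 13764 of the genes are protein-coding. Pseudogenes and multigene families, such as KRT16P6, AK4P3, RPS12P26 and the histone genes, share sequence with near-identical copies, and their values are uncertain where reads could be assigned to either copy. Neighbouring genes on opposite strands could share reads as well, since the strand setting is unknown.

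Genes with at least 1 RPKM in at least 2 libraries were tested (15794 genes, 505 left out). The main test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend) on the deposited log2 values, with 1 model of group means over all 12 libraries, 6 residual degrees of freedom and 3.89 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the genes tested, separately for each comparison, and a gene was called at an adjusted p under 0.05. All adjusted p-values of single genes below are from this fit. Fold changes are differences of mean log2 RPKM, and the error given with each is its standard error (SE) in the same fit.

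The comparisons were GelMA (mean of 5% and 7.5%) with collagen in each line, 7.5% with 5% GelMA in each line, each concentration with collagen, the difference between the lines in the first 2 kinds of effect (PANC1 effect minus BXPC3 effect), and PANC1 with BXPC3 over all matrices. The comparisons, the tests, the filter, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, apart from those described as chosen later.

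There were 46 gene lists, written from textbook knowledge, with 950 entries of which 855 had a gene in the table and 844 were tested. They covered matrix and adhesion (integrins and collagen receptors, collagens, basement membrane, cross-linking enzymes, proteases, hyaluronan and proteoglycans), mechanical signalling (YAP/TAZ targets, actin and SRF targets, mechanosensitive channels), cell state, metabolism, stress, signalling, proliferation and cell type markers. The 44 lists with at least 5 tested genes were tested with camera in limma, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The endothelial markers (4 genes) and the acinar and endocrine markers (2 genes) were only counted. The lists of mitochondrially encoded genes, cytosolic ribosomal proteins and histones were included to stand for RNA quality. Camera was also run with the correlation estimated for each list. With it, 0 lists were called in any of the 7 main comparisons, although 8, 7, 2, 4, 3, 6 and 3 lists had an unadjusted p under 0.05 in the order in which those comparisons are described. Most called lists are therefore given with both adjusted p-values, or with the count of lists called at the estimated correlation. For many lists the members called when p-values were adjusted over the list alone are also counted.

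Genes are named by a fixed rule. In each comparison within a line these were the 6 highest and 6 lowest log2 fold changes (5 and 5 between lines) among called genes that changed at least 2-fold, had a group mean of at least 3 RPKM and had libraries that did not overlap between the groups. From each list called by camera or with at least 3 called members, up to 4 called members with the smallest p-values and up to 2 uncalled members could be named. CDH1, VIM, CCN1, CCN2, MMP14, CD44, ITGB1, FN1, MKI67 and CDKN1A are given in every comparison of GelMA with collagen, and SMAD4 in every library. Some genes that the rule would name are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

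The fit was tested on simulated data with 200 changed genes among 15794. Of genes changed by 0.5, 1 and 2 log2, it recovered 56.1, 80.6 and 94% for GelMA against collagen in BXPC3 and 50, 77.6 and 97% in PANC1. For 7.5% against 5% GelMA it recovered 37.9, 73.1 and 97% in BXPC3 and 50, 70.1 and 92.5% in PANC1. The shares were 33.3, 70.1 and 85.1% for the line difference in GelMA against collagen, 42.4, 62.7 and 86.6% for that in 7.5% against 5%, and 69.7, 92.5 and 97% between the lines. False calls made up 3.14% to 7.49% of the calls in these simulations. The simulated noise was independent between genes and no quantile normalization was applied. Far more genes were called in most real comparisons, so these shares may not hold for the real data.

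The alternatives were no filter, a filter at 5 RPKM, log2(RPKM + 1), log2(RPKM + 0.1), median scaling, a second quantile normalization over the tested genes, eBayes without a trend and with robust estimation, the replicate number as a block, only the libraries of the cell line, and leaving out 1 library at a time. Removing the gene length and GC trend of each library within its line (natural splines with 5 degrees of freedom each) was added after the data were seen. All 15794 tested genes had a length and a GC content from GENCODE 29. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.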

Results

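Gene expression was profiled by poly-A RNA sequencing in 12 libraries of 2 established human pancreatic ductal adenocarcinoma lines grown inside hydrogels. BXPC3 is an epithelial line that lacks a functional SMAD4 gene, and PANC1 is a poorly differentiated line with mesenchymal traits. Each line was placed in a collagen gel or in a gel of gelatin methacryloyl (GelMA), gelatin to which methacryloyl groups are attached so that it can be cross-linked, at 5% or 7.5%. Every group held 2 libraries, so GelMA was represented by 4 libraries per line and collagen by 2. The series concerns the mechanical and biological surroundings of this tumour. The stiffness of the gels, the time in culture and the origin of the replicates are not given in the sources used here. P-values therefore measure only the spread between these libraries, which may be technical. The values were quantile normalized log2 RPKM for 16299 genes, of which 15794 were tested, and the sequencing depth is unknown.

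SMAD4, which encodes a mediator of TGF-beta signalling, was at -5.92 to -5.35 log2 RPKM in the 6 BXPC3 libraries and at 3.94 to 4.55 in the 6 PANC1 libraries, as the line labels require. The leading principal component of all libraries held 94.6% of the variance and separated the lines. Within each line the leading component separated collagen from GelMA, with 51.2% of the variance in BXPC3 and 66.8% in PANC1. Replicates of a group correlated at 0.9922 to 0.9950 across genes. The standard deviation of their difference was 0.295 to 0.364 log2, largest for BXPC3 in collagen, and no pair of libraries was identical.

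In BXPC3, genes of the hypoxia response and of glycolysis were lower in GelMA than in collagen, and genes of cholesterol synthesis were higher. CA9, a carbonic anhydrase induced by low oxygen (ENSG00000107159, chromosome 9, 35673856 to 35681159), fell most, by 6.98 ± 0.40 log2 (SE, adjusted p = 6.17e-06), from a mean of 4.97 log2 RPKM in collagen to -2.02 and -1.98 in 5% and 7.5% GelMA. EGLN3, an oxygen-sensing prolyl hydroxylase, fell by 3.51 ± 0.24 (adjusted p = 1.21e-05). HMGCS1, an early enzyme of the mevalonate pathway, rose by 1.24 ± 0.04 (adjusted p = 4.28e-07), and ACTBL2, a beta-actin-like gene, rose by 2.22 ± 0.22 (adjusted p = 8.02e-05). Of 15794 genes, 5703 were called, 3068 higher and 2635 lower in GelMA. Of these, 198 rose and 228 fell at least 2-fold.

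Other large rises in BXPC3, among genes with a group mean of at least 3 RPKM, were in DIO3, which inactivates thyroid hormone (2.17 ± 0.10), the growth factor gene BMP7 (1.84 ± 0.09), AFF2 (1.82 ± 0.59), the amino acid transporter gene SLC6A20 (1.77 ± 0.29) and IFITM10 (1.76 ± 0.11). Other large falls were in PNCK, a calmodulin-dependent kinase gene (-4.14 ± 0.29), PPFIA4 (-3.83 ± 0.22), EGLN3, the keratin pseudogene KRT16P6 (-3.14 ± 0.36) and RNF183 (-2.96 ± 0.32). On the log2(RPKM + 1) scale the fold change was -4.70 for CA9, -2.54 for PNCK, -2.01 for KRT16P6 and 1.13 for SLC6A20, and all 4 stayed called. The call of AFF2 (adjusted p = 0.0363) was lost when any 1 of the 6 BXPC3 libraries was left out, with adjusted p up to 0.173.

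Among the genes followed in both lines for GelMA against collagen, CCN1 and CCN2, matricellular genes that respond to YAP, rose in BXPC3. The rises were 1.04 ± 0.07 (adjusted p = 1.21e-05) and 1.21 ± 0.15 (adjusted p = 0.000224). CDKN1A, a cell cycle inhibitor, rose by 0.52 ± 0.06 and the hyaluronan receptor gene CD44 by 0.12 ± 0.03. MMP14, the membrane-bound collagenase, fell by 0.44 ± 0.05 (adjusted p = 0.000189). E-cadherin (CDH1) was at -0.11 ± 0.05, vimentin (VIM) at -0.25 ± 0.15, the collagen receptor subunit ITGB1 at -0.04 ± 0.05, fibronectin (FN1) at -0.24 ± 0.20 and the proliferation marker MKI67 at -0.01 ± 0.09. None of these last 5 passed the test.

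Of 25 hypoxia response genes in BXPC3, 22 fell and 0 rose (22 and 0 adjusted over the list alone). Their median was -0.83, with camera adjusted p = 9.66e-16. They included the mTOR inhibitor DDIT4 (-1.21 ± 0.05), the collagen prolyl hydroxylase P4HA1 (-1.41 ± 0.06) and the mitophagy receptor BNIP3L (-1.07 ± 0.06), while ADM (0.13) and CA12 (-0.20) did not pass. Of 19 glycolysis genes, 15 fell and 1 rose (16 and 1 adjusted over the list alone), among them LDHA (-1.13 ± 0.09) and ENO2 (-1.75 ± 0.15), with camera adjusted p = 1.88e-09. PKM (-0.03) and HK1 (-0.06) did not pass. Of 12 matrix cross-linking genes, 7 fell and 1 rose, also adjusted over the list alone, including the lysyl hydroxylase PLOD2 (-1.62 ± 0.06) and the lysyl oxidase LOXL2 (-1.30 ± 0.11), with camera adjusted p = 0.000944. Of 25 cholesterol synthesis genes, 21 rose and 0 fell (22 and 0 adjusted over the list alone), including SQLE (0.87 ± 0.04) and ACAT2 (0.81), with camera adjusted p = 1.73e-13. For each of these 4 lists, adjusted p = 0.26 with an estimated correlation.

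Genes of DNA replication and ribosome assembly also rose in BXPC3. Of 30 G1/S and DNA replication genes, 24 rose and 0 fell (29 and 0 adjusted over the list alone), including the licensing factor CDC6 (0.43 ± 0.04) and the replicative helicase gene MCM2 (0.41), with camera adjusted p = 1.59e-09 and adjusted p = 0.369 with an estimated correlation. Of 29 G2/M and mitosis genes, 14 rose and 0 fell by either adjustment (adjusted over the list alone or over all genes), with camera adjusted p = 0.000944 and adjusted p = 0.555 with an estimated correlation. BIRC5 (0.27) and CDC20 (0.25) rose, while TOP2A (-0.09) did not pass. Of 20 ribosome biogenesis genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone), including DKC1 (0.38) and RRP9 (0.56), with camera adjusted p = 9.55e-08 and adjusted p = 0.26 with an estimated correlation. Of 12 heat shock genes, 10 rose and 0 fell, also adjusted over the list alone, led by HSPB1 (0.52 ± 0.04), with camera adjusted p = 6.5e-05 and adjusted p = 0.26 with an estimated correlation. Of 40 cytosolic ribosomal protein genes, 18 fell and 2 rose (18 and 3 adjusted over the list alone), such as RPS24 (-0.48 ± 0.04) and RPS18 (-0.44). Their camera adjusted p = 0.000475, and adjusted p = 0.477 with an estimated correlation.

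Contractile and lipid genes followed. Of 23 actin and SRF target genes, 15 rose and 2 fell, also adjusted over the list alone, including the myosin light chain MYL9 (1.38 ± 0.12) and TAGLN (1.36 ± 0.14), with camera adjusted p = 0.000475 and adjusted p = 0.26 with an estimated correlation. Of 11 fatty acid synthesis genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone), including the fatty acid synthase gene FASN (1.14 ± 0.15), with camera adjusted p = 0.000475 and adjusted p = 0.477 with an estimated correlation. Of 23 NRF2 targets, 12 rose and 0 fell, also adjusted over the list alone (PGD 0.56), with camera adjusted p = 0.00118 and adjusted p = 0.555 with an estimated correlation. Of 12 Wnt targets, 4 rose and 0 fell (8 and 0 adjusted over the list alone), including the transcription factor TCF7 (0.84 ± 0.08), with camera adjusted p = 0.00262 and adjusted p = 0.26 with an estimated correlation.

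Of 26 interferon response genes in BXPC3, 10 fell, 0 rose and 16 did not pass, with the same 10 and 0 adjusted over the list alone, including IFI6 (-0.70 ± 0.11) and XAF1 (-0.52). Camera gave adjusted p = 0.000475, and adjusted p = 0.477 with an estimated correlation. Of 18 integrins and collagen receptors, 7 fell and 0 rose, also adjusted over the list alone, including the fibronectin receptor subunit ITGA5 (-0.56 ± 0.06) and ITGB4 (-0.35), with camera adjusted p = 0.0205 and adjusted p = 0.369 with an estimated correlation. Higher lists near the threshold were the NF-kB targets (12 of 29 rose, 2 fell; LIF 0.83 ± 0.04), immediate early genes (9 of 27 rose, 3 fell; KLF6 0.80 ± 0.04) and nuclear oxidative phosphorylation genes (12 of 31 rose, 2 fell; CYC1 0.47). Adjusted over the list alone, 13, 11 and 13 of these rose. Their camera adjusted p = 0.0108, 0.0296 and 0.0188, and adjusted p = 0.452, 0.452 and 0.555 with an estimated correlation. The NF-kB and immediate early calls were lost without BXPC3 collagen replicate 1 (adjusted p = 0.102 and 0.146, alternatives other than the estimated correlation spanning 0.000412 to 0.102 and 0.00954 to 0.146), and the oxidative phosphorylation call was lost without replicate 2 (0.0902, the highest of 0.01 to 0.0902). Without that replicate 2, 3623 genes were called in this comparison.

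The other 26 tested lists were not called in BXPC3. The trefoil factor genes of the classical tumour subtype fell (TFF3 -2.50 ± 0.21, TFF2 -2.87 ± 0.32, TFF1 -1.73 ± 0.29), yet only 4 of the 15 classical genes did (4 adjusted over the list alone; camera adjusted p = 0.0933, adjusted p = 0.452 with an estimated correlation). Of 23 YAP/TAZ targets, 7 rose and 6 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.909, adjusted p = 0.942 with an estimated correlation), CCN1, CCN2 and GADD45A (0.75 ± 0.05) among the higher ones. Of 16 collagens, 3 rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.628, adjusted p = 0.758 with an estimated correlation), with COL5A3 at 1.49 ± 0.19 and COL6A1 at -0.67 ± 0.04. The epithelial (4 of 27 rose, 1 fell) and mesenchymal markers (2 of 16 rose, 2 fell) had camera adjusted p = 0.7 for either list, and adjusted p = 0.836 with an estimated correlation. Median, mean and test direction differed in sign in 4 of the 44 lists here, none of them called. Fibroblast and stellate markers (1 of 5 rose, 1 fell) and immune markers (0 of 5 called) had camera adjusted p = 0.464 and 0.503. None of the 4 endothelial markers was called.

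**Figure D1:**
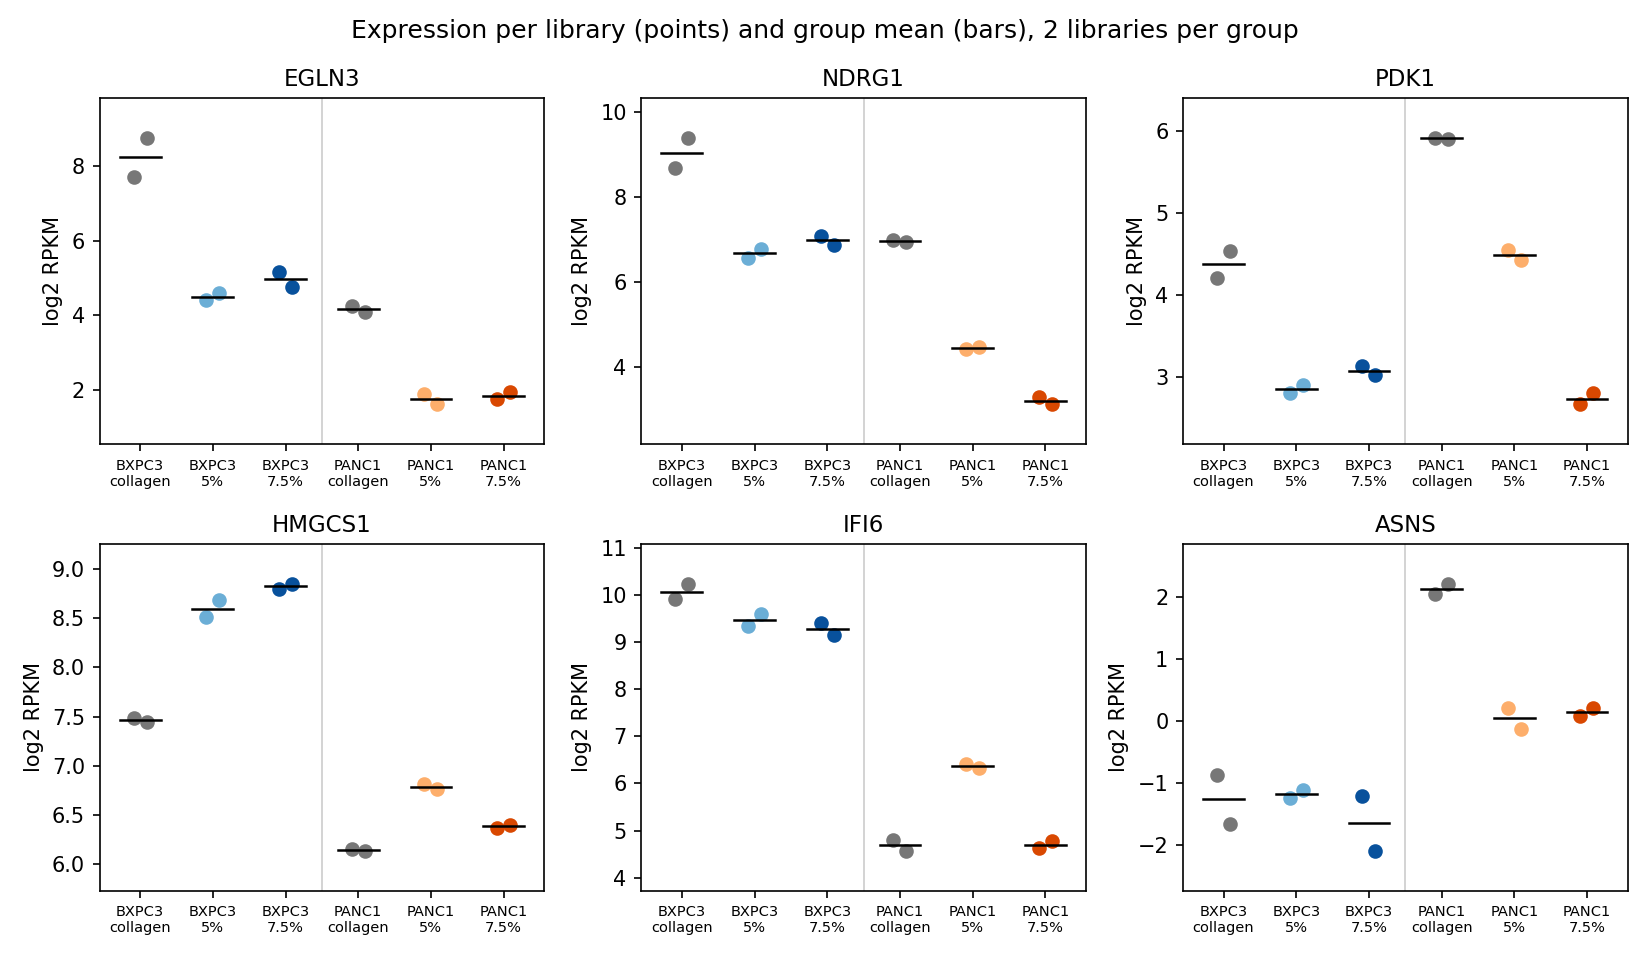
Expression (log2 RPKM, y axis) of 6 genes in each of the 12 libraries (points) by line and matrix (x axis, collagen or percent GelMA), with the mean of 2 libraries as a bar; EGLN3, NDRG1 and PDK1 of the hypoxia response were higher in both collagen libraries of a line than in its 4 GelMA libraries, and HMGCS1 was lower. The interferon-induced IFI6 was highest in 5% GelMA in PANC1 and in collagen in BXPC3.

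In PANC1 the hypoxia response fell further, and genes of amino acid supply, the ribosome and the unfolded protein response fell with it, while interferon response genes rose, mostly in 5% GelMA. SLC2A3, the glucose transporter GLUT3 (ENSG00000059804, chromosome 12, 7919230 to 7936275), fell by 6.14 ± 0.34 log2 (adjusted p = 3.53e-07). TAC3, which encodes the neuropeptide neurokinin B (ENSG00000166863, chromosome 12, 57010000 to 57028883), rose by 6.82 ± 0.48 (adjusted p = 1.88e-06), from -4.59 log2 RPKM in collagen to 1.99 and 2.46 in 5% and 7.5% GelMA. VEGFA, the main angiogenic growth factor, fell by 2.40 ± 0.06 (adjusted p = 2.61e-09). CD24, a surface glycoprotein used as a progenitor marker, rose by 3.01 ± 0.07 (adjusted p = 1.49e-09). In this line 8700 genes were called, 4372 higher and 4328 lower in GelMA, with 756 and 643 at least 2-fold.

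Other large rises in PANC1 were in the fatty acid receptor gene FFAR4 (4.26 ± 0.30), GLIS1 (3.84 ± 0.38), SOWAHB (3.47 ± 0.17), TRBC2 (3.35 ± 0.58) and the focal adhesion gene TNS4 (3.28 ± 0.18). Other large falls were in PCDH15 (-4.49 ± 0.25), CA9 (-3.97 ± 0.40), butyrylcholinesterase (BCHE, -3.90 ± 0.21), ceruloplasmin (CP, -3.66 ± 0.20) and the adenylate kinase gene AK4 (-3.32 ± 0.16). On the log2(RPKM + 1) scale, TAC3 was at 2.44, GLIS1 at 2.51, TRBC2 at 2.11, TNS4 at 1.82, SLC2A3 at -3.14, CA9 at -1.79 and BCHE at -2.06, all still called. TRBC2 was at 1.89 without PANC1 collagen replicate 2.

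Of the followed genes, CCN1 rose by 1.48 ± 0.07 in PANC1 (adjusted p = 1.37e-07), CDKN1A by 0.63 ± 0.06, CDH1 by 0.51 ± 0.05 and CD44 by 0.39 ± 0.03. MMP14 fell by 1.17 ± 0.05 (adjusted p = 8.35e-08) and ITGB1 by 0.18 ± 0.05 (adjusted p = 0.00807). CCN2 (0.24 ± 0.15), VIM (0.07 ± 0.15), FN1 (-0.45 ± 0.20) and MKI67 (0.18 ± 0.09) did not pass.

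Of 25 hypoxia response genes in PANC1, 24 fell and 0 rose (24 and 1 adjusted over the list alone), with a median of -2.13 and camera adjusted p = 1.89e-15. DDIT4 was at -2.49 ± 0.05, P4HA1 at -2.17 ± 0.06 and BNIP3L at -1.98, while CA12 (0.58) did not pass. Of 19 glycolysis genes, 18 fell and 1 rose, also adjusted over the list alone, including GPI (-2.11 ± 0.07), HK2 (-2.38 ± 0.08) and the lactate exporter SLC16A3 (-1.59 ± 0.04), with camera adjusted p = 7.2e-11. Of 24 ATF4 targets, the genes of the amino acid response, 22 fell and 0 rose, also adjusted over the list alone, including MTHFD2 (-0.92 ± 0.03) and PCK2 (-1.23 ± 0.07), with camera adjusted p = 4.4e-11. Of 40 cytosolic ribosomal protein genes, 34 fell and 0 rose (35 and 0 adjusted over the list alone), including RPL27 (-0.73 ± 0.05). The list had a median of -0.39 and camera adjusted p = 7.9e-12. RPS2 (0.01) and RPLP0 (-0.08) did not pass. For each of these 4 lists, adjusted p = 0.247 with an estimated correlation.

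Of 20 unfolded protein response genes in PANC1, 14 fell and 1 rose, also adjusted over the list alone, including the endoplasmic reticulum chaperone HSPA5 (-0.74 ± 0.05) and the stress factor DDIT3 (-1.37 ± 0.07), with camera adjusted p = 0.00017. Of 12 matrix cross-linking genes, 10 fell and 1 rose, also adjusted over the list alone, including the transglutaminase TGM2 (-1.18 ± 0.07) and PLOD2 (-0.92), with camera adjusted p = 0.000298. Adjusted p = 0.247 with an estimated correlation for either of these lists. Of 23 NRF2 targets, 15 fell and 2 rose, also adjusted over the list alone, including heme oxygenase (HMOX1, -2.82 ± 0.12) and the cystine transporter SLC7A11 (-1.52 ± 0.13). Camera gave adjusted p = 0.000544, and adjusted p = 0.712 with an estimated correlation.

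Of 26 interferon response genes in PANC1, 18 rose and 2 fell, also adjusted over the list alone, including OASL (2.35 ± 0.14), IFIT3 (1.86 ± 0.11) and ISG15 (1.44 ± 0.10). MX2 was among the lower (-0.67). Their median was 0.66, camera adjusted p = 0.000327, and adjusted p = 0.617 with an estimated correlation. Against collagen the median was 1.21 in 5% GelMA and 0.09 in 7.5% GelMA. At 7.5% the list was not called (10 rose, 4 fell, camera adjusted p = 0.417). Of 25 cholesterol synthesis genes, 20 rose and 0 fell, also adjusted over the list alone, including SQLE (0.95) and ACAT2 (0.92), with camera adjusted p = 1.42e-07 and adjusted p = 0.53 with an estimated correlation. SREBF2 (0.02) and INSIG1 (-0.12) did not pass. Of 12 Wnt targets, 7 rose and 1 fell (8 and 1 adjusted over the list alone), including the feedback inhibitors AXIN2 (1.66 ± 0.17) and DKK1 (1.13), with camera adjusted p = 0.0106 and adjusted p = 0.293 with an estimated correlation. Of 14 replication-dependent histone genes, 7 rose and 2 fell (8 and 2 adjusted over the list alone), including the linker histone H1-2 (1.33 ± 0.11), with camera adjusted p = 0.0111 and adjusted p = 0.617 with an estimated correlation. Of 13 mitochondrially encoded genes, 8 rose and 0 fell, also adjusted over the list alone, including MT-ND3 (1.07 ± 0.06), with camera adjusted p = 0.0172 and adjusted p = 0.247 with an estimated correlation. MT-CO1 and MT-CO2 were at 0.00, ranks at the top of the table being given equal values by quantile normalization.

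The other 32 tested lists were not called in PANC1. Of 16 collagens, 6 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.878, adjusted p = 0.921 with an estimated correlation), with COL1A1 at 1.66 ± 0.06 and COL3A1 at -2.62 ± 0.10. Of 18 integrins and collagen receptors, 3 rose and 10 fell (3 and 11 adjusted over the list alone; camera adjusted p = 0.0947, adjusted p = 0.605 with an estimated correlation), with the laminin receptor subunit ITGB4 at -1.52 ± 0.05. Of 15 classical subtype genes, 6 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.29, adjusted p = 0.712 with an estimated correlation), including AGR2 (1.24 ± 0.09) and the transcription factor GATA6 (1.33 ± 0.12). On average the classical genes were at -1.76 log2 RPKM in collagen, -1.37 in 5% and -1.48 in 7.5% GelMA. These averages lie under 1 RPKM, where fold changes depend on the unknown offset. Of 27 epithelial markers, 12 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.444, adjusted p = 0.716 with an estimated correlation), with EPCAM at 1.00 ± 0.06 and CLDN7 at -1.46 ± 0.07. Of 16 mesenchymal markers, 3 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.822, adjusted p = 0.908 with an estimated correlation), with SPARC at 2.40 ± 0.26. Of 23 YAP/TAZ targets, 6 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.659, adjusted p = 0.863 with an estimated correlation). Of 30 G1/S and DNA replication genes, 16 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0618, adjusted p = 0.754 with an estimated correlation). Median, mean and test direction differed in sign in 6 of the 44 lists, none of them called.

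A further group of lists was called by camera in neither line for GelMA against collagen. Of 28 proteases and inhibitors, 3 rose and 7 fell in BXPC3 and 12 rose and 8 fell in PANC1, where TIMP3, a metalloprotease inhibitor, was at 1.71 ± 0.09. Of 20 TGF-beta response genes, 5 rose and 10 fell in BXPC3 and 8 rose and 5 fell in PANC1, with thrombospondin (THBS1) at 1.66 ± 0.03 in PANC1. Basement membrane genes (20 tested) rose in 2 and fell in 4 cases in BXPC3, against 8 and 7 in PANC1. Hyaluronan and proteoglycan genes (17) gave 5 and 6 in BXPC3 and 6 and 4 in PANC1. Notch targets (12) gave 3 and 3 and 4 and 4, with NOTCH3 at -2.32 ± 0.09 in PANC1. Mechanosensitive channels (11) gave 1 and 4 and 3 and 4. Basal-like subtype genes (22) gave 3 and 2 and 7 and 5, and mucins and secreted epithelial proteins (16) 1 and 2 and 5 and 4. Stem cell markers (15) gave 5 and 1 and 6 and 4, p53 targets (18) 8 and 3 and 10 and 2, drug transport genes (17) 6 and 2 and 7 and 2, and autophagy and lysosome genes (23) 8 and 3 and 9 and 6. Antigen presentation (14) gave 1 and 2 and 5 and 3, pancreatic transcription factors (8) 1 and 1 and 3 and 3, and metallothioneins (7) 0 and 2 and 2 and 4. Fibroblast and stellate markers in PANC1 (2 of 5 rose, 1 fell) had camera adjusted p = 0.707, and immune markers (1 of 5 rose) 0.581. Of the acinar and endocrine markers 1 of 2 fell in either line, and of the 4 endothelial markers 1 rose and 1 fell in PANC1.

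**Figure D2:**
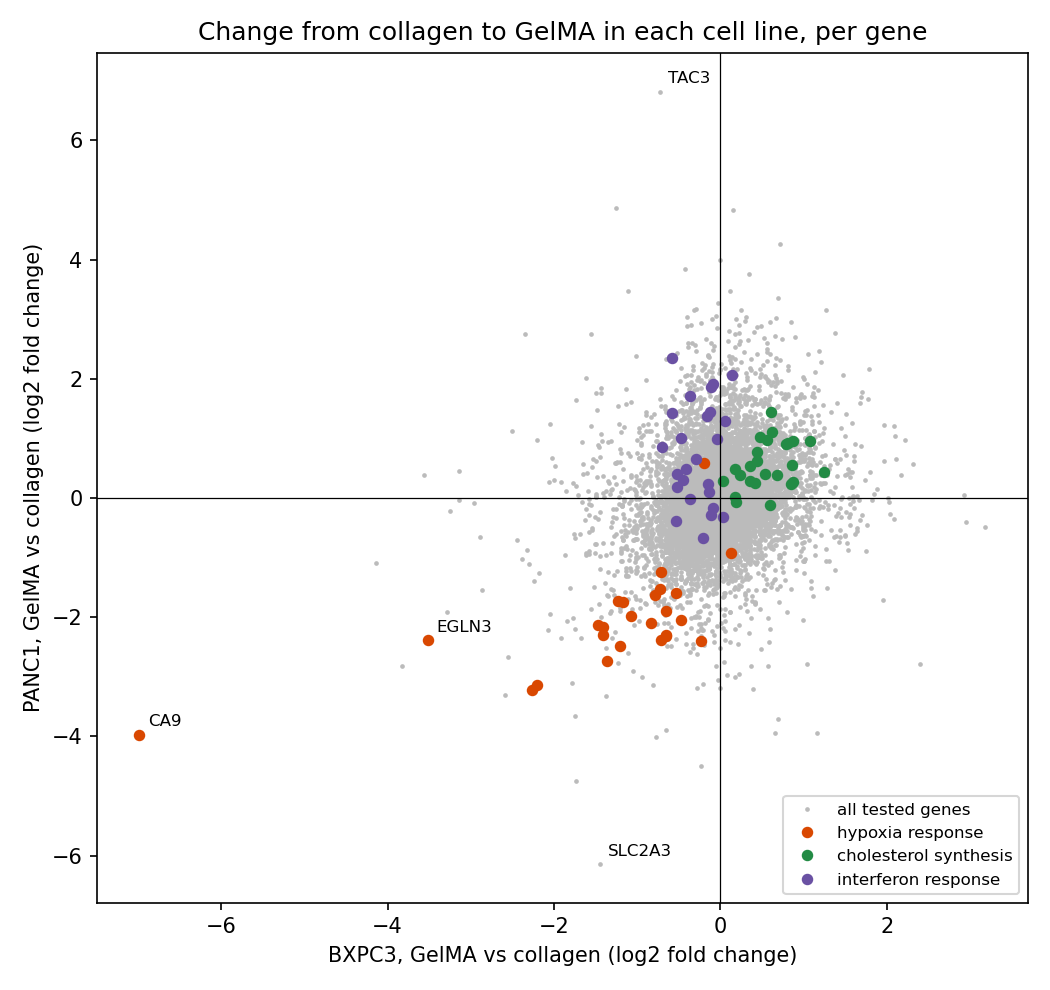
Log2 fold change from collagen to GelMA for each of the 15794 tested genes (points) in BXPC3 (x axis) and PANC1 (y axis), with members of 3 lists in colour. Hypoxia response genes lie to the lower left, with medians of -0.83 and -2.13, cholesterol synthesis genes to the upper right (0.56 and 0.49), and interferon response genes mostly to the left of and above the origin (-0.19 and 0.66).

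Genes called in both lines often shared a direction. Higher in GelMA in both lines were 1425 genes (849 for independent lists, 1-sided Fisher's exact p = 1.47e-137) and lower in both were 1337 (722 for independent lists, p = 4.93e-174), while 1007 were called in opposite directions (1570 for independent lists). At 2-fold or more, 43 were higher in both (9.48 for independent lists) and 78 lower in both (9.28 for independent lists), with 27 in opposite directions (19 for independent lists). The comparisons share no libraries, but genes are not independent of one another. Each gene also had the same residual spread in both lines, from 1 model, which favours calls in both. The counts for independent lists and the Fisher p-values are therefore no measure of agreement beyond chance. Across all genes the fold changes of the lines correlated with Pearson's r = 0.25 and Spearman's rho = 0.28, and with 0.23 and 0.27 without the hypoxia and glycolysis genes. The latter values still cover 15752 of 15794 genes, so they could hardly differ. They cannot decide whether the shared changes go beyond the response to low oxygen. Genes are not replicates, so no p is given for these correlations.

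Each concentration set against collagen alone gave 4720 genes at 5% and 4701 at 7.5% in BXPC3. Leaving out 1 library lowered these to as few as 3047 and 2610. In PANC1, 7293 genes were called at 5% and 8495 at 7.5%. At least 2-fold changes numbered 452 and 416 in BXPC3 and 1185 and 1730 in PANC1. A difference between such counts is not a test of the concentrations, which follows.

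Between 7.5% and 5% GelMA, few genes differed in BXPC3. ATF3, a transcription factor of the stress response (ENSG00000162772, chromosome 1, 212565334 to 212620777), fell by 1.04 ± 0.13 (adjusted p = 0.0336), from 1.79 to 0.75 log2 RPKM, and was the only gene that met the rule for large changes. COL13A1, a transmembrane collagen, was at 1.79 ± 0.25 (adjusted p = 0.0364) with group means of -6.47 and -4.68 log2 RPKM, far under 1 RPKM. Of 15794 genes, 13 were called, 7 higher and 6 lower at 7.5%, against 1493 with an unadjusted p under 0.05. Chosen after their values were seen, the kinase gene PIM1 (-0.43 ± 0.06), the polarity gene PARD6B (-0.53 ± 0.07) and the cytochrome gene CYP1B1 (0.43 ± 0.06) were called genes well above 1 RPKM. The count was 0 with log2(RPKM + 1), 0 with log2(RPKM + 0.1), 0 with only the libraries of the line, 1 with the replicate number as a block and between 6 and 33 when 1 of the 4 libraries was left out. The call of ATF3 was lost with log2(RPKM + 1) (adjusted p = 0.0879), with log2(RPKM + 0.1) (0.0595), by eBayes without a trend, with the block (0.0763), with only the libraries of the line (0.442) and without 3 of the 4 libraries, namely GelMA 5% replicate 1 and either replicate of GelMA 7.5%, its adjusted p over all left-out libraries reaching 0.115.

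Camera called 12 lists between the concentrations in BXPC3, all with small medians and with at most 1 called member. Interferon response genes (26 tested) had a median of -0.18 and camera adjusted p = 6.85e-06, NRF2 targets (23) -0.22 and 4.35e-06, and unfolded protein response genes (20) -0.06 and 0.000115. Adjusted over the list alone, 0, 0 and 3 of these fell and 0 rose. Adjusted p = 0.563, 0.603 and 0.372 with an estimated correlation. Also lower were fatty acid synthesis (-0.17, camera adjusted p = 0.00444), ATF4 targets (-0.09, 0.00466), autophagy and lysosome (-0.06, 0.00632), epithelial markers (-0.11, 0.00735) and histones (-0.11, 0.0156), with 0, 2, 2, 6 and 1 members lower when adjusted over the list alone and adjusted p = 0.563 for epithelial markers and 0.603 for the others with an estimated correlation. Higher were ribosome biogenesis (0.09, camera adjusted p = 3.68e-05), collagens (0.10, 0.0237), glycolysis (0.09, 0.0418) and Notch targets (0.13, 0.0432), with 0, 3, 0 and 0 members higher when adjusted over the list alone. For these, adjusted p = 0.691 for glycolysis and 0.563 for the other 3 lists with an estimated correlation. Over the alternatives the median of NRF2 targets ran from -0.40 to -0.06, and most of the others also moved by over 1.5 times. Leaving out GelMA 5% replicate 1 ended 7 of the 12 calls, including NRF2 targets (adjusted p = 0.242) and ribosome biogenesis (0.204), and of all 12 lists the interferon and unfolded protein response lists alone kept their calls whichever library was left out.

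In PANC1, 7.5% GelMA had lower interferon, hypoxia and glycolysis genes and higher amino acid response genes than 5% GelMA. CYP1A1, a cytochrome that metabolizes aromatic hydrocarbons (ENSG00000140465, chromosome 15, 74719542 to 74725610), rose by 2.43 ± 0.28 (adjusted p = 0.000314), from 0.78 to 3.20 log2 RPKM. AK4, a mitochondrial adenylate kinase induced by low oxygen, fell by 3.41 ± 0.19 (adjusted p = 6.67e-06). OAS1, an antiviral enzyme induced by interferon, fell by 1.83 ± 0.11 (adjusted p = 8.39e-06), and SLC7A5, a large amino acid transporter, rose by 0.82 ± 0.08 (adjusted p = 0.000155). In all, 2956 genes were called, 1446 higher and 1510 lower at 7.5%, of which 139 and 213 at least 2-fold.

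Other large rises at 7.5% in PANC1 were in VIPR1, a neuropeptide receptor gene (2.15 ± 0.20), TNS4 (2.01 ± 0.20), the hyaluronan-degrading CEMIP (1.71 ± 0.10), PPP1R16B (1.70 ± 0.27) and PARM1 (1.67 ± 0.26). Other large falls were in CP (-2.91 ± 0.24), the pseudogene AK4P3 (-2.81 ± 0.18), which resembles AK4, the chemokine gene CXCL2 (-2.78 ± 0.17), PPFIA4 (-2.58 ± 0.26) and PPP1R3G (-2.47 ± 0.22).

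Of 26 interferon response genes in PANC1, 20 fell at 7.5% and 0 rose (21 and 0 adjusted over the list alone), including BST2 (-1.43 ± 0.10), with a median of -0.86, camera adjusted p = 1.42e-15 and adjusted p = 0.274 with an estimated correlation. Of 19 glycolysis genes, 15 fell and 1 rose (17 and 1 adjusted over the list alone), including ALDOC (-2.23 ± 0.15), with camera adjusted p = 5.6e-14 and adjusted p = 0.274 with an estimated correlation. Of 25 hypoxia response genes, 16 fell and 2 rose (17 and 2 adjusted over the list alone), including PDK1 (-1.76 ± 0.11) and ANGPTL4 (-2.19 ± 0.16), while DDIT4 (-0.03) and ADM (-0.07) did not pass. Their camera adjusted p = 4.47e-10, and adjusted p = 0.432 with an estimated correlation. Of 24 ATF4 targets, 15 rose and 1 fell (18 and 1 adjusted over the list alone), including SLC3A2 (0.63) and PHGDH (0.66), with camera adjusted p = 1.67e-08 and adjusted p = 0.427 with an estimated correlation. Of 40 ribosomal protein genes, 14 rose and 0 fell (20 and 2 adjusted over the list alone), including RPS19 (0.25 ± 0.04), with camera adjusted p = 8.05e-06 and adjusted p = 0.517 with an estimated correlation.

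Of 25 cholesterol synthesis genes in PANC1, 14 fell at 7.5% and 0 rose (15 and 1 adjusted over the list alone), including INSIG1 (-0.92 ± 0.09), with camera adjusted p = 2.39e-09 and adjusted p = 0.432 with an estimated correlation. Of 11 fatty acid synthesis genes, 8 fell and 0 rose (8 and 2 adjusted over the list alone), including the desaturase FADS2 (-1.18 ± 0.09), with camera adjusted p = 6.42e-05 and adjusted p = 0.524 with an estimated correlation. Of 29 NF-kB targets, 12 fell and 2 rose (14 and 2 adjusted over the list alone), including the adhesion molecule ICAM1 (-1.09 ± 0.05), with camera adjusted p = 7.14e-05 and adjusted p = 0.427 with an estimated correlation. Of 14 antigen presentation genes, 4 fell and 0 rose (7 and 0 adjusted over the list alone), including CD74 (-1.16 ± 0.17), with camera adjusted p = 0.000276 and adjusted p = 0.432 with an estimated correlation. Matrix cross-linking (5 of 12 fell, 6 adjusted over the list alone; TGM2 -1.50 ± 0.08) and actin genes (8 of 23 fell, 8 adjusted over the list alone; MYL9 -0.96 ± 0.14) were called lower, and ribosome biogenesis (8 of 20 rose, 9 adjusted over the list alone; BOP1 0.32) and histones (2 of 14 rose, 2 adjusted over the list alone; H4C8 0.42) higher. Their camera adjusted p = 0.00023, 0.00206, 0.00023 and 0.0174, and adjusted p = 0.339, 0.274, 0.489 and 0.539 with an estimated correlation. The histone call was lost without PANC1 GelMA 5% replicate 1 (adjusted p = 0.0679) or GelMA 7.5% replicate 2 (0.105, the highest of its alternatives other than the estimated correlation), and 1449 to 1746 genes were called when any 1 of the 4 libraries was left out.

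**Figure D3:**
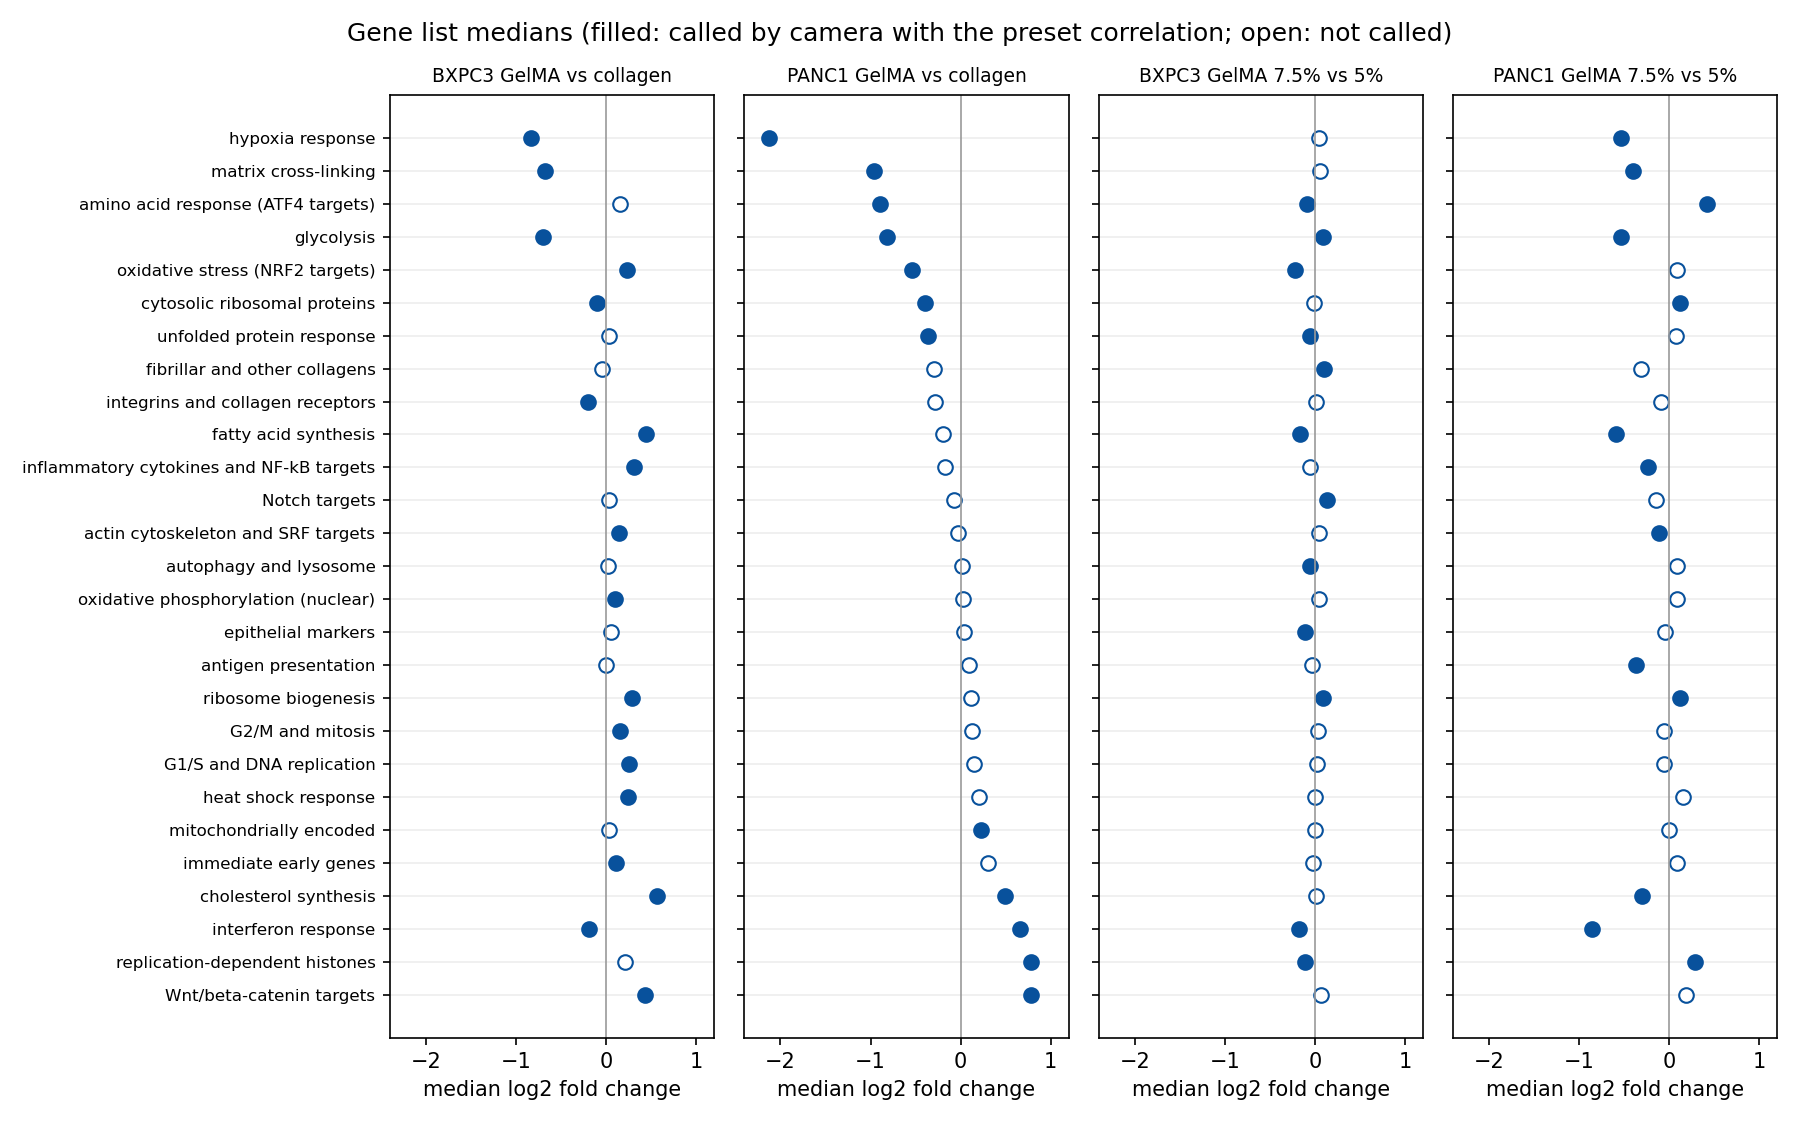
Median log2 fold change (x axis) of the gene lists called by camera in at least 1 of the 4 comparisons within a line (y axis, lists), with filled points for a call at the preset correlation and open points for none. In the panel for 7.5% against 5% GelMA in BXPC3 every point lies near 0. In PANC1 the interferon response list has a median of 0.66 for GelMA against collagen and -0.86 for 7.5% against 5%. The baselines of these medians differ, and the PANC1 libraries in 7.5% GelMA were at 0.07 and 0.20 against collagen.

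The effect of GelMA differed between the lines for 6181 genes, 2925 with a more positive change in PANC1 and 3256 with a more negative one. Large positive differences (PANC1 effect minus BXPC3 effect) were in TAC3 (7.55 ± 0.68, adjusted p = 2.46e-05), the mucin gene MUC2 (5.11 ± 1.18), the vessel growth factor ANGPT2 (4.69 ± 0.56), the pseudogene ECEL1P1 (4.32 ± 0.33) and GLIS1 (4.27 ± 0.54). Large negative ones were in the Wnt antagonist SFRP5 (-5.19 ± 0.52), DMBT1 (-5.11 ± 1.13), SLC2A3 (-4.68 ± 0.48), CYP4F11 (-4.40 ± 0.40) and PCDH15 (-4.26 ± 0.35). All 10 genes lie under 1 RPKM in at least 1 group, and on the log2(RPKM + 1) scale TAC3 was at 2.49, MUC2 at 2.08, ANGPT2 at 1.81, DMBT1 at -1.39 and CYP4F11 at -1.61, still called.

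Of 24 ATF4 targets, 21 had a more negative change in PANC1 and 0 a more positive one (22 and 0 adjusted over the list alone; MTHFD2 -1.22 ± 0.05), with camera adjusted p = 2.95e-12 and adjusted p = 0.394 with an estimated correlation. For the hypoxia response it was 22 and 2 of 25 (22 and 3 adjusted over the list alone; VEGFA -2.17 ± 0.08), camera adjusted p = 6.04e-08, and adjusted p = 0.486 with an estimated correlation. For the interferon response 19 of 26 were more positive in PANC1 and 1 more negative (20 and 1 adjusted over the list alone; OASL 2.92 ± 0.20), camera adjusted p = 2.44e-07, and adjusted p = 0.464 with an estimated correlation. Ribosomal protein genes (27 of 40 more negative, 28 adjusted over the list alone; RPL19 -0.64 ± 0.06) and NRF2 targets (18 of 23, 18 adjusted over the list alone; HMOX1 -3.19 ± 0.16) had camera adjusted p = 4.17e-07 each, and adjusted p = 0.469 and 0.561 with an estimated correlation. Glycolysis (12 of 19 more negative, 12 adjusted over the list alone; SLC16A3 -1.14 ± 0.05) and the unfolded protein response (13 of 20, 15 adjusted over the list alone; DDIT3 -2.01 ± 0.10) had camera adjusted p = 1.09e-05 and 5.94e-05, and adjusted p = 0.464 and 0.364 with an estimated correlation. The remaining called lists were fatty acid synthesis, NF-kB targets and ribosome biogenesis, more negative in PANC1, and mitochondrially encoded genes, histones and the classical subtype, more positive (AGR2 1.57 ± 0.13, TFF3 3.63 ± 0.30). Their camera adjusted p = 0.00186, 0.0146, 0.0214, 0.0228, 0.0287 and 0.03, and adjusted p = 0.67, 0.561, 0.67, 0.394, 0.67 and 0.464 with an estimated correlation. Quantile normalization holds mitochondrially encoded genes near the top of the values, so their line difference may reflect that limit. The classical subtype genes averaged -1.76 to -1.37 log2 RPKM in the PANC1 groups, where fold changes depend on the unknown offset. Calls lost when 1 library was left out were those of the classical subtype (without BXPC3 collagen replicate 2, adjusted p = 0.076, or PANC1 GelMA 7.5% replicate 1, 0.0518), histones (without BXPC3 collagen replicate 2, 0.093, or PANC1 GelMA 5% replicate 2, 0.0575) and NF-kB targets (without BXPC3 collagen replicate 1, 0.0545).

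The effect of the GelMA percentage differed between the lines for 1417 genes, 634 more positive and 783 more negative in PANC1. The count was 659 to 1314 when 1 of the 8 GelMA libraries was left out, and 941 by eBayes without a trend. AK4 (-3.80 ± 0.26, adjusted p = 0.000135) and CP (-3.15 ± 0.33, adjusted p = 0.000787) had a more negative change in PANC1, and CYP1A1 (2.49 ± 0.39, adjusted p = 0.00474) a more positive one. In BXPC3, AK4 was at 0.39 and CP at 0.24, neither called. The other genes named by size were TMEM204 (2.96 ± 0.39), ADAMTS12 (2.82 ± 0.66), LAMC3 (2.73 ± 0.37), DIPK1B (2.37 ± 0.39), the potassium channel gene KCNK3 (-5.03 ± 0.97), CA9 (-4.88 ± 0.66) and SLC2A3 (-4.51 ± 0.55). Each of these 7 lies under 1 RPKM in 1 or both GelMA groups of a line. On the log2(RPKM + 1) scale, calls were lost for TMEM204 (-0.20, adjusted p = 0.278), ADAMTS12 (0.65, 0.18), LAMC3 (0.23, 0.172), DIPK1B (0.03, 0.913) and CA9 (-1.31, 0.0823), while KCNK3 (-2.30, 4.03e-05) and SLC2A3 (-0.52, 0.0352) stayed called. Leaving out 1 library also ended the calls of ADAMTS12 (adjusted p up to 0.0938) and KCNK3 (up to 0.0519, without BXPC3 GelMA 7.5% replicate 1).

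Of 19 glycolysis genes, 15 had a more negative response to the percentage in PANC1 and 0 a more positive one (17 and 0 adjusted over the list alone; ALDOC -2.38 ± 0.21), camera adjusted p = 2.18e-15, and adjusted p = 0.324 with an estimated correlation. The interferon response (11 of 26 more negative, 15 adjusted over the list alone; OAS1 -1.62 ± 0.15) and ATF4 targets (13 of 24 more positive, 19 adjusted over the list alone; SLC3A2 0.75 ± 0.09) had camera adjusted p = 3.08e-10 each, and adjusted p = 0.324 with an estimated correlation. Hypoxia response (14 of 25 more negative, 17 adjusted over the list alone; PDK1 -1.98 ± 0.15) and cholesterol synthesis (9 of 25, 16 adjusted over the list alone; HMGCS1 -0.63 ± 0.07) had camera adjusted p = 1.05e-09 and 1.04e-08, and adjusted p = 0.388 with an estimated correlation. In all, 17 lists were called, 6 more positive and 11 more negative in PANC1. With an estimated correlation camera called 0 of the 44 (6 at an unadjusted p under 0.05). The calls of Notch targets (camera adjusted p = 0.0287) and collagens (0.0396) were lost when 1 library was left out. For Notch targets these were BXPC3 GelMA 5% replicate 1 (adjusted p = 0.0753), BXPC3 GelMA 7.5% replicate 1 (0.0801) and PANC1 GelMA 7.5% replicate 2 (0.055), and for collagens BXPC3 GelMA 5% replicate 2 (0.0775) and PANC1 GelMA 5% replicate 1 (0.0639).

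Averaged over the matrices, the lines differed in 14502 of 15794 genes, 7891 higher and 6611 lower in PANC1, with 3616 and 3287 at least 2-fold. Among the largest differences, the keratin gene KRT6A (ENSG00000205420, chromosome 12, 52487174 to 52493257) was lower in PANC1, at -15.51 ± 0.24 (adjusted p = 7.42e-13). Also lower were the keratin gene KRT5 (-14.82 ± 0.27), the adhesion molecule CEACAM5 (-14.21 ± 0.38), the protease TMPRSS4 (-14.17 ± 0.32) and SERPINB3 (-12.86 ± 0.17). Higher in PANC1 was PSAP, which encodes the precursor of lysosomal saposins (ENSG00000197746, chromosome 10, 71816298 to 71851375), at 16.78 ± 0.07 (adjusted p = 3.55e-16). So were the long noncoding RNA MEG3 (14.37 ± 0.10), the arginine deiminase PADI2 (14.21 ± 0.57), the receptor tyrosine kinase RET (13.32 ± 0.37) and the kinesin KIF1A (13.09 ± 0.60). The lower line was far under 1 RPKM for each of these 10 genes, and on the log2(RPKM + 1) scale they were at -11.65 to -7.95 and 6.55 to 11.32. Their order changed with the scale, KRT5 being at -11.65 and KRT6A at -10.81, PADI2 at 9.50 and MEG3 at 7.65. The median difference over all genes was 0.117.

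Of 22 basal-like subtype genes, 21 were lower in PANC1 and 1 higher, also adjusted over the list alone (KRT7 -8.06 ± 0.04, SPRR1B -12.49 ± 0.13), with camera adjusted p = 1.8e-06 and adjusted p = 0.0834 with an estimated correlation. Of 26 interferon response genes, 25 were lower and 1 higher, also adjusted over the list alone (OAS1 -5.24 ± 0.06), with camera adjusted p = 1.81e-06 and adjusted p = 0.649 with an estimated correlation. Of 27 epithelial markers, 22 were lower and 5 higher, also adjusted over the list alone (CDH1 -3.76 ± 0.03), with camera adjusted p = 0.000113 and adjusted p = 0.306 with an estimated correlation. Of 15 classical subtype genes, 12 were lower and 0 higher, also adjusted over the list alone (CEACAM6 -12.49 ± 0.11, GATA6 -4.16 ± 0.08), with camera adjusted p = 0.002 and adjusted p = 0.367 with an estimated correlation. Of 16 mucins and secreted epithelial proteins, 15 were lower and 1 higher, also adjusted over the list alone (LCN2 -9.01 ± 0.11, MUC3A 5.59 ± 0.13), with camera adjusted p = 0.00058 and adjusted p = 0.649 with an estimated correlation. Of 29 G2/M and mitosis genes, 27 were higher in PANC1 and 0 lower, also adjusted over the list alone (BUB1 1.70 ± 0.03), with camera adjusted p = 0.000179 and adjusted p = 0.837 with an estimated correlation. Of 20 ribosome biogenesis genes, 17 were higher and 3 lower, also adjusted over the list alone (FBL 3.93 ± 0.02), with camera adjusted p = 0.00708 and adjusted p = 0.837 with an estimated correlation. Mesenchymal markers (10 of 16 higher, 5 lower; median 3.41, 1.71 to 3.47 over the alternatives) and TGF-beta response genes (14 of 20 higher, 5 lower; CCN2 7.28 ± 0.10) were not called as lists, with camera adjusted p = 0.318 and 0.178, and adjusted p = 0.837 and 0.649 with an estimated correlation.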

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

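Of the tests in this part, those of the interferon, hypoxia and ribosomal protein lists and the splits of the libraries were set out before their results were seen, and removal of the length and GC trend was added after the data were seen. The results in the next 4 paragraphs drew attention because the same contrast differed between BXPC3 and PANC1 in a test of the difference itself, except for 5 followed genes whose difference did not pass. Each value is the effect in PANC1 minus that in BXPC3, in log2 (median of the members for lists).

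For GelMA against collagen, the difference was called for 6181 genes and 13 lists. With an estimated correlation camera called 0 lists (3 at an unadjusted p under 0.05). The list medians were -0.99 for ATF4 targets, -0.93 for the hypoxia response, 0.95 for the interferon response and -0.24 for ribosomal proteins. NRF2 targets were at -0.72, glycolysis at -0.51, the unfolded protein response at -0.32, fatty acid synthesis at -0.77, NF-kB targets at -0.71 and ribosome biogenesis at -0.22. More positive in PANC1 were mitochondrially encoded genes (0.29), histones (0.49) and the classical subtype (0.80). Mitochondrially encoded genes lie near the top of the values, where quantile normalization leaves little room for change. Against collagen their median was 0.00 or 0.01 in the BXPC3 GelMA libraries and 0.23 in each PANC1 GelMA library. A difference in response cannot be told apart from this limit. The classical subtype genes averaged under 1 RPKM in PANC1, where the unknown offset matters. Over the alternatives the medians ran from -0.79 to -0.41 for NF-kB targets and 0.35 to 0.86 for histones, that of the classical subtype was as low as 0.41, and these 3 calls were lost without single libraries.

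Among single genes the differences for GelMA against collagen were TAC3 7.55, MUC2 5.11, ANGPT2 4.69, ECEL1P1 4.32, GLIS1 4.27, SFRP5 -5.19, DMBT1 -5.11, SLC2A3 -4.68, CYP4F11 -4.40 and PCDH15 -4.26. On the log2(RPKM + 1) scale these 10 stayed called, at 2.49, 2.08, 1.81, 2.76, 2.53, -3.35, -1.39, -3.03, -1.61 and -3.37. Of the genes followed throughout, CDH1 (0.62 ± 0.07), CCN1 (0.43 ± 0.10), CCN2 (-0.98 ± 0.21), MMP14 (-0.73 ± 0.07) and CD44 (0.27 ± 0.05) differed between the lines. The difference did not pass for VIM (0.31, adjusted p = 0.286), ITGB1 (-0.13, 0.125), FN1 (-0.20, 0.608), MKI67 (0.19, 0.268) and CDKN1A (0.11, 0.369).

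For 7.5% against 5% GelMA, the difference was called for 1417 genes (659 to 1314 when 1 library was left out) and 17 lists. Camera with an estimated correlation called 0 lists (6 at an unadjusted p under 0.05). The medians were -0.67 for glycolysis, 0.48 for ATF4 targets, -0.63 for the interferon response, -0.62 for the hypoxia response, -0.29 for cholesterol synthesis and 0.27 for NRF2 targets. Ribosomal proteins were at 0.12, cross-linking at -0.53, NF-kB targets at -0.32, histones at 0.43, antigen presentation at -0.36 and actin genes at -0.17. Fatty acid synthesis was at -0.51, the unfolded protein response at 0.14, immediate early genes at 0.16, Notch targets at -0.32 and collagens at -0.48. Over the alternatives the interferon median ran from -0.85 to -0.40, NRF2 targets from 0.21 to 0.44, cross-linking from -0.61 to -0.34, antigen presentation from -0.44 to -0.20 and immediate early genes from 0.10 to 0.19. The calls of Notch targets and collagens were lost without single libraries.

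Single genes for 7.5% against 5% were TMEM204 2.96, ADAMTS12 2.82, LAMC3 2.73, CYP1A1 2.49, DIPK1B 2.37, KCNK3 -5.03, CA9 -4.88, SLC2A3 -4.51, AK4 -3.80 and CP -3.15. With log2(RPKM + 1) the call was lost for TMEM204 (-0.20), ADAMTS12 (0.65), LAMC3 (0.23), DIPK1B (0.03) and CA9 (-1.31). It was kept for CYP1A1 (1.96), KCNK3 (-2.30), SLC2A3 (-0.52), AK4 (-3.34) and CP (-2.75). ADAMTS12 and KCNK3 also lost it without single libraries.

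Hypoxia and glycolysis genes were lower in GelMA than in collagen in both lines. After removal of the length and GC trend of each library, the list medians were 0.98 to 1.02 times those before, which argues against such a trend. Against random lists matched on expression, each of the 4 medians lay at percentile 0 (random medians -0.11 to 0.12 for hypoxia in BXPC3), which argues against a shift of genes of that level by quantile normalization. Without BXPC3 collagen replicate 2 the hypoxia median in BXPC3 was -0.72, so that library alone was not the source. Lower oxygen inside the collagen cultures may be a biological explanation, and oxygen was not measured here.

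Ribosomal protein genes were lower in GelMA in PANC1, with a median of -0.39. The median after removal of the length and GC trend was 0.98 times that before. It lay at percentile 0 of random lists matched on expression, whose medians ran from -0.10 to 0.15, so neither a length trend nor quantile normalization of one expression level accounts for it. The ribosomal protein, mitochondrially encoded and histone lists were set in advance to stand for RNA quality. All were called in this comparison at the preset correlation. A difference in RNA quality was not tested and cannot be told apart from an effect of the matrix. No biological explanation was tested.

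The interferon list moved in opposite directions in the lines, -0.19 in BXPC3 (-0.29 to -0.16 over the alternatives) and 0.66 in PANC1. The rise in PANC1 lay mostly in 5% GelMA (medians of 1.24 and 1.16 in its libraries against collagen, 0.07 and 0.20 at 7.5%). Many members are low in PANC1, where the unknown offset matters. For the 16 of 26 members with a mean of at least 5 RPKM in both lines, the median difference was 0.99. Its matched-list permutation p = 0.0001 was the smallest that 10000 lists can give. The mean was over all libraries of a line, so a member could pass through 5% GelMA, where the list was high in PANC1. The matched lists were not filtered in this way, so this test cannot decide whether the offset is the source. The whole list lay at percentile 100 of random lists matched on expression in both lines, whose medians ran from -0.16 to 0.30. The biological cause stays open.

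Between the lines, 14502 genes were called. Of the 108 possible splits of the libraries that exchange them within each matrix, 100 were drawn, and 1 of 100, the real split itself, called as many. The highest of the other splits called 12006. The leading principal component already separated the lines, and every other split mixes them. The real split was therefore bound to call the most genes, and no conclusion is drawn from this test.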

How the results depend on the processing

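The removal of the length and GC trend was chosen after seeing the data, and the other alternatives were fixed before. Counts of genes stayed within 1.5 times the reported count under the 11 alternatives that leave out no library, in each comparison for which they were run, with these exceptions. The fit with only the libraries of a line was not run for comparisons between lines, nor removal of the length and GC trend for PANC1 against BXPC3. For 7.5% against 5% GelMA in BXPC3 (13 genes), the counts were 8 with a filter at 5 RPKM, 0 with log2(RPKM + 1), 0 with log2(RPKM + 0.1), 0 with only the libraries of the line (limma, against 1493 genes at an unadjusted p under 0.05 among the reported tests) and 1 with the replicate number as a block. For the line difference in 7.5% against 5%, 941 genes were called by eBayes without a trend, against 1417. The cause was not tested. Replicate numbers showed no sign of a shared batch, as the deviations of replicates correlated at -0.05 to 0.08 over 15 pairs of groups. Of the libraries, 6 of 12 correlated best with their own number. The 2 libraries of a group deviate from its mean as mirror images and always give the same answer, so the 12 are not separate outcomes. A check of replicate numbers cannot show a batch that separates collagen from GelMA. Whether the matrices were handled together is not given in the sources used here. Such a batch could not be told apart from an effect of the matrix.

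With an estimated inter-gene correlation, 0 gene lists were called for GelMA against collagen in BXPC3 and 0 in PANC1, 0 for 7.5% against 5% in BXPC3 and 0 in PANC1, 0 for the line difference in GelMA, 0 for that in 7.5% against 5% and 0 between the lines.

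Leaving out 1 library leaves 1 in its group, which is then assumed to vary like the other groups. The counts of genes then ran from 3623 to 5324 for GelMA against collagen in BXPC3, the lowest without BXPC3 collagen replicate 2. They ran from 3047 to 4336 for 5% against collagen in BXPC3 (3047 without collagen replicate 2, 3134 without GelMA 5% replicate 1) and from 2610 to 4314 for 7.5% against collagen in BXPC3 (2610 without GelMA 7.5% replicate 2). For 7.5% against 5% they ran in BXPC3 from 6 (without GelMA 5% replicate 1) to 33 (without GelMA 5% replicate 2), and in PANC1 from 1449 to 1746. In PANC1 these were 1594 and 1449 without GelMA 5% replicates 1 and 2, and 1746 and 1614 without GelMA 7.5% replicates 1 and 2. The line difference in 7.5% against 5% ran from 659 to 1314. It was 797 without BXPC3 GelMA 5% replicate 1, 659 and 815 without BXPC3 GelMA 7.5% replicates 1 and 2, 687 and 686 without PANC1 GelMA 5% replicates 1 and 2, and 873 and 745 without PANC1 GelMA 7.5% replicates 1 and 2. Lists called for 7.5% against 5% in BXPC3 ran from 7 (without GelMA 5% replicate 1) to 11. Fewer libraries were used in each case.

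Of the values for named genes under the alternatives, 24685 kept direction and side of the threshold, 218 passed newly, 521 no longer passed and 2 reversed. TMEM204 was at -0.20 in the line difference in 7.5% against 5% with log2(RPKM + 1) (adjusted p = 0.278), against 2.96. S100P in PANC1 at 7.5% against 5% ran from -0.86 to 0.51 when 1 library was left out, with 0.51 (adjusted p = 0.0154) without PANC1 GelMA 5% replicate 1. Of the values for gene lists, 3587 were unchanged in this sense, 68 passed newly and 127 no longer passed, of which 92 with the estimated correlation. The other 2 reversed, both for 7.5% against 5% in BXPC3. The G1/S list had medians from -0.05 to 0.10 and the G2/M list from -0.06 to 0.09, the lower values without BXPC3 GelMA 5% replicate 1 (adjusted p = 0.00105 and 0.00237). The cause was not tested. Depth is unknown, so its limits cannot be given.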

Other observations

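The tests in this part, of the aryl hydrocarbon receptor targets and of neighbouring genes, were chosen after the values were seen, as were the genes named here. Genes that are in neither the hypoxia nor the glycolysis list also changed at least 2-fold in GelMA in both lines, and only some are given here. Each had to reach a mean of at least 3 RPKM in only 1 of the 6 groups. Some may therefore lie under 1 RPKM in a line, where the fold change depends on the unknown offset. Absence from the lists does not make a gene unrelated to low oxygen. AK4, described above as induced by low oxygen, is in neither list and was lower in both lines. Higher were the transcription factor CREB5 (1.70 ± 0.17 in BXPC3, 1.78 ± 0.17 in PANC1), the endothelial lipase LIPG (1.47 ± 0.09, 2.06 ± 0.09), the glycoprotein GPNMB (1.37 ± 0.11, 2.77 ± 0.11), the gel-forming mucin MUC5AC (1.69 ± 0.44, 1.69 ± 0.44) and the protease MMP7 (1.45 ± 0.23, 1.18 ± 0.23). Lower were placental growth factor PGF (-1.92 ± 0.15, -2.34 ± 0.15), the growth factor carrier IGFBP3 (-1.78 ± 0.34, -3.11 ± 0.34), CP (-1.75 ± 0.20, -3.66 ± 0.20) and the gelatinase MMP9 (-1.38 ± 0.38, -2.51 ± 0.38).

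In PANC1, known targets of the aryl hydrocarbon receptor, a sensor of planar aromatic compounds, were higher at 7.5% than at 5% GelMA. CYP1A1 (2.43 ± 0.28), CYP1B1 (1.29 ± 0.06), TIPARP (1.18 ± 0.05), ALDH3A1 (2.01 ± 0.25) and SERPINB2 (1.15 ± 0.22) passed, ALDH3A1 and SERPINB2 under 1 RPKM. AHRR (0.10), NQO1 (0.38) and UGT1A6 (-0.06) did not pass. The median of the 8 tested genes was 1.17, at percentile 100 of random lists matched on expression (-0.21 to 0.21), and it was 1.15 without CYP1A1. The list was written because CYP1A1 had been seen to lead, so this test cannot decide, and activation of the receptor in PANC1 at 7.5% may be a hypothesis at most. In BXPC3 CYP1B1 alone was called (0.43 ± 0.06, adjusted p = 0.0467), a call lost with log2(RPKM + 1), log2(RPKM + 0.1) or only the libraries of the line, and the other 7 were at -0.46 (NQO1) to -0.02 (SERPINB2). The line difference for CYP1A1 was 2.49 ± 0.39.

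Genes next to SMAD4 and PSAP were low together in BXPC3. Under 0.25 RPKM in BXPC3 and at 1 RPKM or more in PANC1 were 4 neighbours on chromosome 18 (ME2, ELAC1, SMAD4, MEX3C) and 7 on chromosome 10 between 71396934 and 72235860 (CDH23, VSIR, PSAP, CHST3, SPOCK2, ASCC1, ANAPC16). In 1000 shuffles of gene order, 0 gave a run as long as the 7 genes around PSAP, the longest having 5. A run of 4 as around SMAD4 is within the longest runs that shuffles gave anywhere. A run at SMAD4 itself, a gene named in advance, was not tested. Loss of these regions from the BXPC3 genome may be an explanation, untested here because no DNA was measured. Runs are not specific to it: of the 8 runs of 5 or more genes, 4 were low in PANC1, including the gene families from FLG to PGLYRP4 (12 genes) and from SERPINB5 to SERPINB2 (6 genes). The other 3 low in BXPC3 ran from TMPRSS2 to ZBTB21 (6 genes), KLHL9 to LINC01239 (5 genes) and ZNF418 to ENSG00000176593 (5 genes).

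On chromosome 19, neighbouring genes were high together in PANC1. Over windows of 11 neighbours among 12748 genes expressed in both lines, the highest median line difference was 3.87, from PAF1 to FBL (39385852 to 39846414), against at most 2.40 in 1000 shuffles of gene order. PLEKHG2 (4.78), MED29 (3.91) and SUPT5H (3.21) lay in it, and RPS16 differed by 1.62. An earlier form of this test, over all tested genes, had placed its top window on chromosome 10 around PSAP, and the limit to genes expressed in both lines was set after that. A gain of this region in PANC1 may be an explanation, with no DNA measured. The lowest window, at -2.52, lay within the shuffles (-2.91).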
